A study of Mus musculus with 4 samples.

How the data were processed

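Tumours grown from SCC7 cells, a mouse squamous carcinoma line, under the skin of C3H/HeN mice were profiled by bulk RNA sequencing in 2 control and 2 anti-CD71 libraries, each from a tumour taken on day 10. RNA extraction with TRIZOL and library preparation were done by BGI, per the labels' protocols. The deposited values are TPM, a transcript abundance scaled to a fixed total per library, per RefSeq transcript, written to the nearest hundredth. The genome build was GRCm38.p6, per the submitters' processing notes. The aligner and the program that estimated the TPM values are not given in the sources used here. TPM keeps no depth, so the number of reads behind each value is unknown and no counting interval or detection floor is given.

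The files of both controls and of anti-CD71 replicate 2 each listed 59881 transcripts, and their values summed to 999999.29, 999998.88 and 1000000.86. The file of anti-CD71 replicate 1, as used here, ended inside a line after 13587 transcripts, in the same order as in the other files. Its last line was not used, which left 13586 transcripts, or 22.69% of those in the other files. The values of these shared transcripts summed to 233326.01 and 232700.72 in the controls, 237664.99 in anti-CD71 replicate 1 and 238644.66 in anti-CD71 replicate 2. A transcript beyond the break was treated as missing, not as 0.

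Gene symbols came from a RefSeq gene table of the same build. It matched 58425 of the 59881 transcripts, and the TPM of a gene's transcripts were added, which gave 17574 genes. Transcripts without a symbol held between 1.42% and 1.55% of the TPM of a complete library and were left out. RefSeq copies of 1 gene at a second locus (1744 transcripts) were added to that gene. Reads shared by near-identical genes may have been split between them by the unknown program, so values of granzyme, globin, Bcl2a1, stefin A, thymosin beta 15, histocompatibility and ribosomal pseudogene family members are uncertain.

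Comparisons ran limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with an intensity trend in the variance prior, on genes with at least 1 TPM in 2 or more libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The test, filter, pseudocount, gene lists and rule for naming genes were fixed before the data were examined. The design asked for genes listed in all 4 files. Because the partial file lists some transcripts of a gene and not others, a gene counted as listed where its shared transcripts carried at least 90% of its TPM, averaged over the 3 complete libraries, and the sum over shared transcripts was compared. This limit was chosen after the structure of the files was known and before any test was run. It left 1564 tested genes in the comparison of 4 libraries.

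A second comparison, added after the files were seen, set anti-CD71 replicate 2 alone against the 2 controls over all genes (11982 tested). Here the single treated library is assumed to vary like the controls. Over the 1564 genes listed for all 4 libraries, the SD of the log2 difference was 0.294 between the treated libraries and 0.222 between the controls, which goes against that assumption. Gzmg had an SE of 0.07 over 3 libraries and 0.74 over 4, so standard errors and calls over 3 libraries rest on the spread of the controls alone. The filter of 1 TPM in 2 libraries was kept from the planned comparison. A filter of 1 TPM in 1 library was also run, and the planned one was retained after the counts under both had been seen. The retained filter leaves genes expressed only in the treated library untested, while the other admits genes through the library in which they are high, so the share of a list that is higher depends on it. Genes called lower numbered 286 with the retained filter and 12 with the other, and the median total degrees of freedom were 5.03 and 2.88. The cause of this difference was not tested. Both results are given.

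The 39 gene lists covered pathways and the cell types that a dissected tumour could hold. They held 822 different genes, of which 795 were found, 1 of them by an older symbol. Lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Camera at an estimated correlation takes its degrees of freedom from these few libraries, so hardly any list could pass it. Over 4 libraries the cytosolic ribosome list had an estimated correlation of 0.011, yet its unadjusted camera p went from 0.0138 to 0.133. Failing that test therefore does not show that correlated genes made a call. It does not exclude this either. Estimates for the other lists that passed over 4 libraries were 0.66 (hypoxia), 0.103 (inflammatory cytokine), -0.131 (macrophage) and -0.218 (T cell). Over 3 libraries they ran from -0.143 (neutrophil) to 1 (globin and MHC class II) among lists that passed. Where the estimate exceeds 0.01, the p-value at the preset correlation may be too small. Calls of listed genes are also given adjusted over all lists together, or over a single list where the text says the list alone. The latter does not control error across the lists. Genes named in the text were Tfrc, the 12 called genes with the largest change in each direction among those with a mean of at least 1 TPM, no overlap between the groups and a name other than that of a predicted gene, and the 3 members with the smallest p in each list that passed and in 7 lists fixed beforehand. Some genes that meet this rule are not reported here. Other genes named in the text were picked as further members of a list or of the skin markers after their values were seen.

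The tests were also run on simulated data with known changes. With noise drawn from the fitted variance prior, the comparison of 4 libraries recovered 97% of genes changed 2-fold and 99% of those changed 4-fold among 1550 genes, and 13 of 207 calls were of unchanged genes. The comparison of 3 libraries recovered 68% and 90% among 11877 genes, and 3 of 161 calls were of unchanged genes. These shares hold only where the treated libraries vary as the model assumes. An earlier simulation, with noise from each gene's own variance estimate and no filter, was replaced. In it 47 of 245 calls over 3 libraries (19.2%) and 11 of 209 over 4 libraries (5.3%) were of unchanged genes, and recovery was 98% and 100% over 3 libraries.

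Alternatives covered the normalization, filter, pseudocount, variance model, replicate number as a block, each library left out, the rule for listed genes, and transcripts in place of genes. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The labels do not say that replicates came from separate mice, so p-values of genes measure only the spread between these samples, which may be technical. Camera p-values at the preset correlation compare the genes of a list with all other tested genes under an assumed correlation. They do not measure the spread between tumours.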

Results

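The samples were SCC7 tumours, a transplanted mouse model of head and neck squamous carcinoma, grown under the skin of C3H/HeN mice. Mice of the treated group had received an antibody against CD71, the transferrin receptor through which cells take up iron, on days 6 and 9. Tumours of both groups were harvested on day 10, and RNA sequencing gave 2 control and 2 anti-CD71 libraries. The design asks what the antibody changed in the tumour's transcripts. Values are TPM with an unknown read depth. Anti-CD71 replicate 1 was used in part, with 13586 transcripts, so 1564 genes could be compared over all 4 libraries. A further comparison of anti-CD71 replicate 2 with both controls covered 11982 genes.

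In the comparison of 4 libraries, the chemokine genes Cxcl2 and Ccl3 rose in anti-CD71 tumours and the macrophage genes Csf1r and Cd14 fell. Cxcl2, a chemokine that recruits neutrophils, rose from 5.2 ± 2.81 TPM in controls to 40.96 ± 15.87 TPM in anti-CD71 tumours (SD, n = 2 each; log2 change 2.78, SE 0.38, adjusted p = 0.0386). Ccl3, another inflammatory chemokine, rose from 4.61 ± 0.14 to 30.24 ± 16.72 TPM (log2 change 2.37, SE 0.35, adjusted p = 0.0386). Csf1r, the receptor that macrophages need for survival, fell from 141.35 ± 22.03 to 68.1 ± 1.8 TPM (log2 change -1.03, SE 0.11, adjusted p = 0.0319). Csf1r lies on chromosome 18 from 61105572 to 61131139 and Cxcl2 on chromosome 5 from 90903899 to 90905938 in GRCm38.p6.

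Limma called 14 genes higher and 54 lower in anti-CD71 tumours among the 1564. With median scaling the split was 21 higher and 36 lower. The largest rise was in Stfa2l1, of the stefin A family, listed at 0 in both controls and at 10.4 and 10.7 TPM in the anti-CD71 libraries (log2 change 3.53, adjusted p = 0.000584). After it, Cxcl2 and Ccl3, the next largest rises were in Slpi, an inhibitor of neutrophil proteases (log2 change 1.78), Hdc, which makes histamine (1.51), the stress-response gene Ier3 (1.01), and Adm, which encodes the vasodilator adrenomedullin (0.98). Smaller rises were in Dscc1 (0.58), Col5a3 (0.53), Noct (0.52), Brix1 (0.47) and Eef1e1 (0.45). Among called genes with a mean of at least 1 TPM, Bcl2a1c fell most (log2 change -1.95, adjusted p = 0.00133). It belongs to a family that opposes cell death. Next came Cd83, a marker of activated antigen-presenting cells (-1.33), and Timd4, a macrophage receptor for dying cells (-1.13). Tmem119 (-1.06), Bcl2a1d (-1.06), Ntn4 (-0.86), Was (-0.83), the scavenger receptor gene Stab1 (-0.82), Kif21b (-0.82) and Cyth4 (-0.78) fell as well.

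**Figure D1:**
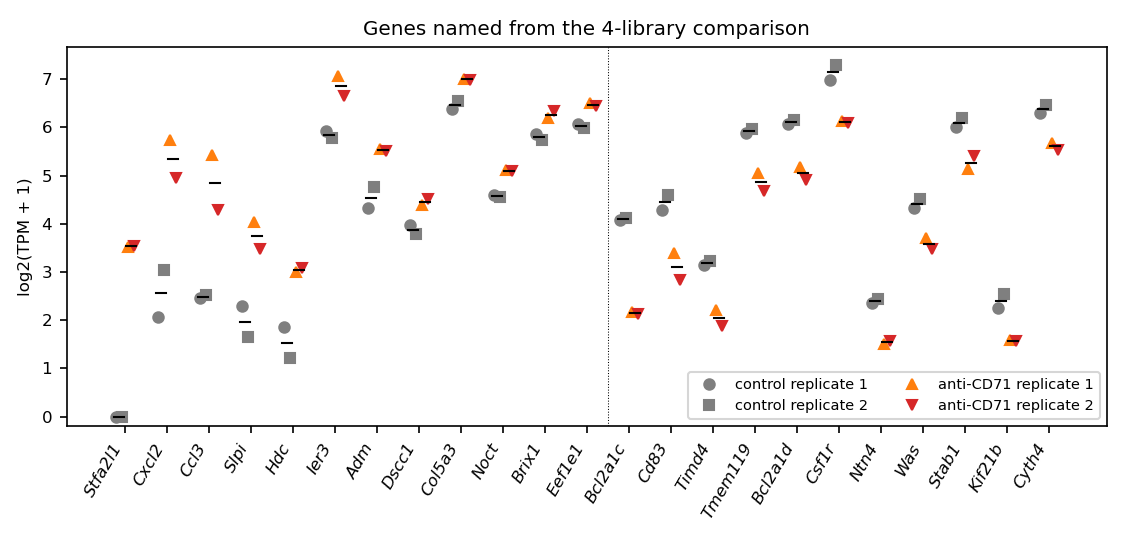
Expression of the genes named from the comparison of 4 libraries, as log2(TPM + 1) on the vertical axis. Each symbol is 1 library, black bars are the means of the 2 libraries of a group, and the dotted line parts genes higher in anti-CD71 tumours (left) from genes lower (right); Csf1r stands at 125.77 and 156.93 TPM in controls against 69.38 and 66.83 TPM in anti-CD71 libraries.

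Among the 12 gene lists with enough genes in all 4 files, 3 rose and 2 fell by camera with the preset correlation. None of these calls held with an estimated correlation (smallest adjusted p = 0.497) or with fry. The former test has few degrees of freedom here, so its failure decides little. The macrophage list fell (adjusted p = 0.0139), and of its 3 tested members Csf1r and Cd14 (log2 change -0.44, adjusted p = 0.0386) fell, while Mertk did not pass (-0.36, adjusted p = 0.113). The T cell list fell (adjusted p = 0.0373) with no called member over all genes, its 3 members being Cd3g (-0.87, adjusted p = 0.065), Icos (-0.65) and Cd5 (-0.49). All 3 members of each of these lists passed when adjusted over the list alone. That is a low bar, since 417 of the 1564 tested genes had an unadjusted p under 0.05 by limma. The adjusted p of each list was 0.497 with an estimated correlation.

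The inflammatory cytokine list rose (adjusted p = 0.0373 and, with an estimated correlation, adjusted p = 0.497), with Cxcl2 and Ccl3 called among 6 members, of which 2 lay below 0, and 4 called when adjusted over the list alone. Ccl7 stood at 377.31 ± 69.24 TPM in controls and 571.64 ± 76.06 TPM in anti-CD71 tumours (adjusted p = 0.0868). The hypoxia list rose (adjusted p = 0.0316 and, with an estimated correlation, adjusted p = 0.61), with Adm called among 5 members, and 3 called when adjusted over the list alone. Its members Higd1a (log2 change 0.29) and the glucose transporter gene Slc2a1 (0.23) did not pass over all genes. The cytosolic ribosome list rose (adjusted p = 0.0373 and, with an estimated correlation, adjusted p = 0.497) by a median log2 change of 0.10 over 11 members, none of which passed, Rps2 (0.20), Rps20 (0.27) and Rps15a (0.18) coming closest. Among other markers tested over 4 libraries, the values of Klrg1 (-1.45, adjusted p = 0.0676), Gzmg (-2.16, adjusted p = 0.148), Ctsg (-1.26), Car2 (-0.89), Irgm2 (0.18) and Gbp2 (0.02) did not pass. The neutrophil gene Stfa3 did not pass either, being listed at 0 in both controls and at 1.11 and 7.89 TPM in the anti-CD71 libraries. Of 84 listed genes tested, 9 were called over all genes and 23 when adjusted over the lists alone.

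These counts rested on both controls: limma called 1 gene higher and 0 lower without control replicate 1 (271 at an unadjusted p under 0.05), and 2 higher and 0 lower without control replicate 2 (171 at an unadjusted p under 0.05). It called 36 higher and 61 lower without anti-CD71 replicate 1, 11 higher and 22 lower without anti-CD71 replicate 2, and 1 higher and 0 lower with no filter on low values (435 at an unadjusted p under 0.05).

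For the antibody's target, Tfrc, which encodes CD71, TPM were 44.11 and 36.16 in the controls and 29.0 in anti-CD71 replicate 2. The difference did not pass the test (log2 change -0.45, SE 0.14, adjusted p = 0.141 by limma over 3 libraries). Tfrc lies on chromosome 16 from 32608896 to 32632794. Only a transcript holding 5.84% of its TPM was listed for anti-CD71 replicate 1, with 3.12 and 2.64 TPM in controls and 0.66 and 0.62 TPM in the anti-CD71 libraries. The antibody binds the protein, so the transcript does not check the treatment.

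Haemoglobin transcripts fell in anti-CD71 replicate 2. Hba-a1, an alpha globin gene on chromosome 11 from 32283672 to 32284486, fell from 2000.12 ± 161.14 TPM in controls (SD, n = 2) to 542.59 TPM (log2 change -1.88, SE 0.08, adjusted p = 0.0034). The beta globin genes Hbb-b1 (log2 change -1.89, adjusted p = 0.0019) and Hbb-b2 (-1.26, adjusted p = 0.027) fell too. The globin list passed with 3 of 4 tested members called and 4 of 4 when adjusted over the list alone (camera adjusted p = 2.46e-05, and adjusted p = 0.69 with an estimated correlation). With a filter of 1 TPM in 1 library it passed too (adjusted p = 0.000585, and adjusted p = 0.671 with an estimated correlation), with 1 of 4 members called. No globin gene was listed for anti-CD71 replicate 1. Alas2, the erythroid enzyme that starts haem synthesis, fell from 9.84 and 10.21 TPM to 3.06 TPM (log2 change -1.44, adjusted p = 0.0199). Over its transcripts listed for all 4 libraries, which carry 80.44% of its TPM, it stood at 7.72 and 8.41 TPM in controls, 5.81 TPM in anti-CD71 replicate 1 and 2.46 TPM in replicate 2.

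Some genes of nucleated erythroid precursors were near 0 in the complete libraries. Slc4a1 was at 0.14, 0.23 and 0.2 TPM, and the erythroid transcription factor gene Klf1 at 0.1, 0 and 0 TPM in control replicate 1, control replicate 2 and anti-CD71 replicate 2. The erythroid precursor list did not pass (adjusted p = 0.0922), with Aqp1 (log2 change -0.45) and Car2 (-1.34), both also expressed outside the erythroid lineage, falling among 6 tested members, and Mgst3 not passing (0.29). The iron handling list did not pass (adjusted p = 0.843).

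**Figure D2:**
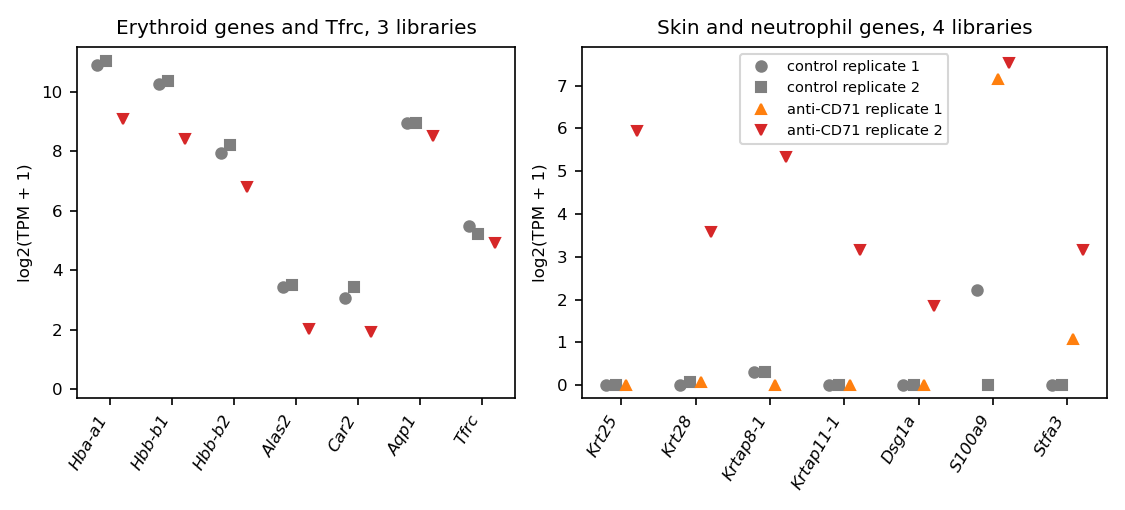
Expression as log2(TPM + 1) on the vertical axes, each symbol being 1 library. Left, erythroid genes and Tfrc in the 3 complete libraries, with Hba-a1 at 1886.18 and 2114.06 TPM in controls and 542.59 TPM in anti-CD71 replicate 2; right, skin and neutrophil genes over the transcripts listed for all 4 libraries, with Krt25 at 60.54 TPM in anti-CD71 replicate 2 and 0 in the other 3.

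Over all genes, granzyme and other genes of killer lymphocytes fell in anti-CD71 replicate 2. Gzmg, a granzyme gene, fell from 361.75 ± 6.38 TPM in controls to 33.35 TPM (log2 change -3.40, SE 0.07, adjusted p = 0.000568), and Prf1, which encodes the pore-forming protein perforin, fell from 51.9 ± 1.75 to 11.16 TPM (-2.12, SE 0.09, adjusted p = 0.0034). The granzyme genes Gzmf (-3.19), Gzmd (-3.10), Gzme (-2.52), Gzmc (-2.48) and Gzma (-2.28) fell too. Of 17 tested genes of the cytotoxic list, 12 fell and 1, Ccl3, rose, against 15 and 2 when adjusted over the list alone (camera adjusted p = 7.02e-13, and adjusted p = 0.69 with an estimated correlation). In the natural killer cell list 4 of 8 fell and 6 when adjusted over the list alone (adjusted p = 4.43e-05, and adjusted p = 0.69 with an estimated correlation), among them Il2rb (-1.97), Ncr1 (-1.71) and Klra7 (-1.71). In the T cell list 1 of 15 fell, Cd3g (-1.12), and 9 when adjusted over the list alone (adjusted p = 0.000257, and adjusted p = 0.69 with an estimated correlation), with Lck (-1.11, adjusted p = 0.0511) and Cd2 (-0.81) not passing. In the list of regulatory and exhausted T cell genes 1 of 11 fell, Havcr2 (-0.82), and 5 when adjusted over the list alone (adjusted p = 0.00126, and adjusted p = 0.69 with an estimated correlation), with Entpd1 (-0.58) and Tnfrsf9 (-0.54) not passing. With the filter of 1 TPM in 1 library these 4 lists passed as well (adjusted p between 5.36e-09 for the cytotoxic and 0.000522 for the regulatory and exhausted T cell list, and adjusted p = 0.671 for each with an estimated correlation), but genes called lower numbered 7 of 19 in the cytotoxic list, 1 of 9 in the natural killer cell list and 0 in the other 2. In anti-CD71 replicate 1 Gzmb and Gzmg lay below both controls by less, with log2 differences of -0.21 and -0.92 against -1.71 and -3.40 in replicate 2. Klrg1 stood at 3.89 TPM in anti-CD71 replicate 1 and 1.41 TPM in replicate 2, against 8.28 and 8.48 TPM in controls. Over 4 libraries Ncr1 (log2 change -1.31, adjusted p = 0.0553) and Cd3g (-0.87, adjusted p = 0.065) did not pass. The cytotoxic list did not pass over 4 libraries either (4 genes, 3 of them below 0, camera adjusted p = 0.506). Counting any listed transcript it did not pass with 6 genes, 5 of them below 0 (camera adjusted p = 0.174). Skin genes were high in anti-CD71 replicate 2, as given below, and whether its composition bears on the lymphocyte and haemoglobin falls was not tested.

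Macrophage, complement and antigen presentation genes were lower in anti-CD71 replicate 2 as well. Of 22 macrophage genes, 12 fell and 1, Cd163 (log2 change 1.26), rose, against 17 and 2 when adjusted over the list alone (adjusted p = 2.37e-07, and adjusted p = 0.69 with an estimated correlation). Msr1 (-0.69) and Itgam (-0.81) were among those that fell, as was Csf1r (-1.06). Of 19 genes for complement and Fc receptors, 14 fell, and 18 when adjusted over the list alone (adjusted p = 3.94e-12, and adjusted p = 0.69 with an estimated correlation), with C1qc falling from 1063.16 ± 179.0 to 423.87 TPM (-1.31), Fcgr2b by -1.06 and Cfb by -0.99. Of 20 MHC class I genes, 7 fell, and 14 when adjusted over the list alone (adjusted p = 8.7e-10, and adjusted p = 0.69 with an estimated correlation), with B2m at -0.58, H2-Q4 at -0.62 and H2-K1 at -0.56. Of 12 MHC class II genes, 2 fell, Ctss (-0.96) and H2-DMb1 (-1.38), and 9 when adjusted over the list alone, with Ifi30 (-0.43, adjusted p = 0.0511) not passing over all genes (list adjusted p = 2.69e-06, and adjusted p = 0.69 with an estimated correlation). With the filter of 1 TPM in 1 library these 4 lists passed as well (adjusted p = 6.47e-06 for macrophages, 4.9e-09 for complement and Fc receptors, 1.26e-08 for MHC class I and 4.74e-05 for MHC class II, and adjusted p = 0.671 for each with an estimated correlation), but 0 of their genes were called over all genes. Adjusted over the list alone, that filter gave 16, 16, 13 and 3 genes lower. H2-Eb1 transcripts listed for all 4 libraries stood at 41.77 and 72.8 TPM in controls and at 21.17 and 22.38 TPM in the anti-CD71 libraries.

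Smaller falls were in the dendritic cell list (2 of 16 called, Cd83 at -1.60 and Irf8 at -0.80, with Itgax not passing at -0.86; 5 when adjusted over the list alone; adjusted p = 0.00509, and adjusted p = 0.69 with an estimated correlation). The interferon gamma response list fell (adjusted p = 0.0036, and adjusted p = 0.69 with an estimated correlation) with 3 of 27 members lower, among them Gbp9 (-0.68) and Irf8, and Nos2 higher (1.54), against 9 and 2 when adjusted over the list alone. In anti-CD71 replicate 1 all 6 members with at least 50% of their TPM listed and a mean of at least 1 TPM lay above the controls, with a median log2 difference of 0.45 against -0.08 for the same genes in replicate 2. Over 4 libraries, counting any listed transcript, the list did not pass and had a mean log2 change of 0.40 (9 genes, camera adjusted p = 0.0991). The immediate early list fell (adjusted p = 0.00995, and adjusted p = 0.69 with an estimated correlation) with 4 of 20 members lower, among them Nr4a1 (-1.58) and Fosb (-1.54), and Ier3 higher (0.80), against 9 and 3 when adjusted over the list alone. With the filter of 1 TPM in 1 library these 3 lists passed (adjusted p = 0.00876 for dendritic cells, 0.00398 for the interferon gamma response and 0.0197 for immediate early genes, and adjusted p = 0.671 for each with an estimated correlation) with 0 genes called over all genes. Outside these lists the kinase gene Sik1 (-2.25), the chemokine receptor gene Cx3cr1 (-2.14) and the ribosomal pseudogene Rpl31-ps12 (-2.38) were among the largest falls. Tmsb15a was at 12.21 and 26.65 TPM in controls and listed at 0 in anti-CD71 replicate 2 (adjusted p = 0.0273). Over its transcripts listed for all 4 libraries it stood at 6.41 TPM in replicate 1 and did not pass (log2 change -2.74, adjusted p = 0.147).

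**Figure D3:**
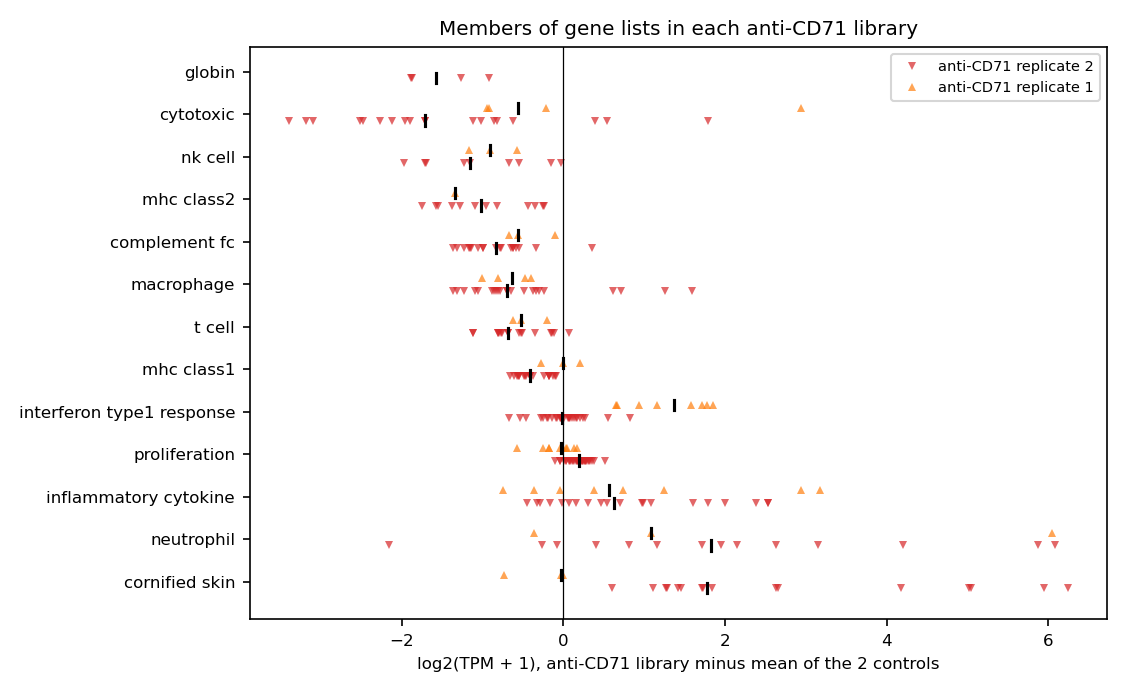
Difference in log2(TPM + 1) between each anti-CD71 library and the mean of the 2 controls (horizontal axis) for the members of 13 gene lists (vertical axis), with symbols for genes and black bars for medians. Replicate 2 shows genes with at least 1 TPM in 1 of its 3 libraries, and replicate 1 those with at least 50% of their TPM listed and a mean of at least 1 TPM; the type I interferon response list had a median of 1.37 in replicate 1, where 8 genes were listed.

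Some inflammatory and neutrophil genes rose in anti-CD71 replicate 2, as did genes of the epidermis. S100a8 rose from 3.34 ± 2.66 TPM in controls to 265.49 TPM (log2 change 6.09, SE 0.53, adjusted p = 0.0206) and S100a9 from 2.75 ± 1.3 to 212.99 TPM (5.88, SE 0.30, adjusted p = 0.00567), both encoding a calcium-binding protein abundant in neutrophils and inflamed skin. The chemokine genes Cxcl1 (2.53) and Cxcl3 (2.53), the cytokine gene Il1b (2.00), its decoy receptor gene Il1r2 (1.95) and the haptoglobin gene Hp (2.51) also rose. The neutrophil list rose with 3 of 7 tested members called, 4 when adjusted over the list alone, while Ctsg fell (-2.16) in both counts (adjusted p = 0.0479, and adjusted p = 0.69 with an estimated correlation). Its median log2 change was 0.40, with 3 of the 7 members below 0. A filter of 1 TPM in 1 library adds 7 members through replicate 2 alone, so its list result is not given as support. With no filter the median was 0.74 over 21 members, 6 of them below 0, with 0 called (adjusted p = 7.48e-06, and adjusted p = 0.68 with an estimated correlation). Over 4 libraries, counting any listed transcript, the neutrophil list did not pass (5 genes, 2 of them below 0 and 0 called; camera adjusted p = 0.0751). The inflammatory cytokine list rose with 4 of 17 called, 6 when adjusted over the list alone (adjusted p = 0.000725, and adjusted p = 0.69 with an estimated correlation). With the filter of 1 TPM in 1 library it rose with 0 of 20 called (adjusted p = 0.001, and adjusted p = 0.671 with an estimated correlation). S100a9 transcripts listed for all 4 libraries stood at 3.67 and 0 TPM in controls, 142.39 TPM in anti-CD71 replicate 1 and 183.5 TPM in replicate 2.

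Genes of the epidermis and hair were high in replicate 2. Lgals7 (log2 change 4.28), Dmkn (3.27), S100a3 (3.07) and Sfn (2.49), genes of stratified epithelium and hair, rose, as did Cfd (2.76), which fat cells secrete. Krt14 was at 0.09 and 0.1 TPM in controls and 36.37 TPM in replicate 2, and Krt5 was listed at 0 in both controls and at 31.4 TPM in replicate 2. The filter of 1 TPM in 2 libraries leaves such genes untested. A filter of 1 TPM in 1 library admits 14 of 16 cornified skin genes and 11 of 25 keratinocyte genes through replicate 2 alone, so the list results with it follow in part from the filter; it called 7 genes higher in each list. With no filter, all 21 cornified skin genes above 0 in a complete library were above both controls in replicate 2, 16 of them by at least 1 TPM. That list rose (adjusted p = 1.74e-18, and adjusted p = 0.68 with an estimated correlation) with 0 genes called over all genes and 19 when adjusted over the list alone. The keratinocyte list rose with no filter (30 genes, 8 below 0 and 0 called; adjusted p = 4.2e-06, and adjusted p = 0.68 with an estimated correlation) and did not pass with 1 TPM in 2 libraries (14 genes, 3 called; adjusted p = 0.138). In anti-CD71 replicate 1 the hair follicle keratin gene Krt25 was listed at 0, Dmkn stood at 1.49 TPM and did not pass over 4 libraries (log2 change 1.80, adjusted p = 0.238), and Krt16 stood at 3.69 TPM against 2.37 and 1.46 TPM in controls and 7.31 TPM in replicate 2.

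Several further lists rose, most by little, though the mast cell and eosinophil list had a median log2 change of 0.99. The proliferation list rose by a median log2 change of 0.19 over 36 genes, with 0 called (adjusted p = 4.89e-06, and adjusted p = 0.69 with an estimated correlation), Cdc20 (0.36), Aurka (0.38) and Mcm5 (0.29) having the smallest p. The cytosolic ribosome list rose (median 0.075 over 32 genes, Rplp1 at 0.24, Rps2 at 0.22 and Rps29 at 0.21; adjusted p = 0.00187, and adjusted p = 0.69 with an estimated correlation). The oxidative phosphorylation list rose (median 0.079 over 28 genes, Cox6c at 0.16, Sdhb at 0.18 and Atp5a1 at 0.11; adjusted p = 0.0294, and adjusted p = 0.69 with an estimated correlation). The mast cell and eosinophil list rose (9 genes; adjusted p = 0.0453, and adjusted p = 0.69 with an estimated correlation) with no gene called, Hdc at 1.54, Cma1 at 1.47 and Mcpt8 at -1.26. With the filter of 1 TPM in 1 library it did not pass (adjusted p = 0.279), and fry put its direction as lower. The hypoxia list rose (19 genes; adjusted p = 0.0479, and adjusted p = 0.872 with an estimated correlation) with no gene called, Adm at 0.96, Bnip3 at 0.39 and Higd1a at 0.37, and did not pass with the filter of 1 TPM in 1 library (adjusted p = 0.103). The lists for endothelium (adjusted p = 0.149), fibroblasts and matrix (0.373), skeletal muscle (0.354), B cells (0.776), adipocytes (0.825), glycolysis (0.46), haem synthesis (0.825) and the type I interferon response (0.843) did not pass. Over 4 libraries the type I interferon response list did not pass either (3 genes, camera adjusted p = 0.14). It rose with the replicate number as a block (camera adjusted p = 0.0334), where no list passed with an estimated correlation (smallest adjusted p = 0.684). The rise lay mainly in replicate 1, with Ifit3 at 331.26 TPM there, 107.25 TPM in replicate 2 and 107.34 and 93.69 TPM in controls. Counting any listed transcript over 4 libraries, camera at the preset correlation called 7 of 30 lists. The cytosolic ribosome (adjusted p = 0.0123), glycolysis (0.0272) and type I interferon response (0.0272) lists rose, and the macrophage (0.000397), complement and Fc receptor (0.00482), MHC class II (0.00482) and natural killer cell (0.0272) lists fell. None of these 7 passed with an estimated correlation (smallest adjusted p = 0.705) or with fry. The inflammatory cytokine (camera adjusted p = 0.0616), T cell (0.129) and hypoxia (0.278) lists, called over the 1564 genes, did not pass when any listed transcript counted.

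Over 3 libraries limma called 57 genes higher and 286 lower in anti-CD71 replicate 2, and 7 lists rose and 12 fell. None of these list calls held with fry or with an estimated correlation, a test with too few degrees of freedom here to decide. With no filter fry called 4 lists higher: cornified skin, keratinocytes, neutrophils and adipocytes. Their median log2 changes were 1.46, 0.57, 0.74 and 0.21. Of 601 listed genes tested, 90 were called over all genes and 188 when adjusted over the lists alone. Of the 343 called genes, 52 were listed for anti-CD71 replicate 1, and 50 of these (96.2%) lay on the same side of the controls there. Unchanged libraries, simulated with shared simulated controls and noise independent between genes, gave a median of 76.9% and at most 90.4% in 100 simulations. Genes that vary together, as those of a shared cell type may, would widen this range. The share of 96.2% is thus not shown to lie beyond chance. With a filter of 1 TPM in 1 library, limma called 60 genes higher and 12 lower, of which 14 were among the 343, and with no filter it called 0 in either direction (3401 at an unadjusted p under 0.05). A single treated library cannot show how anti-CD71 tumours differ from each other.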

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

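Most settings were listed before the data were examined. The rules for listed genes, transcripts in place of genes, and all settings of the comparison of 3 libraries were chosen after the files were seen. Cause was not tested for any change of count below, except where fewer libraries or genes were used. Gbp2 and Irgm2, neither of which passed, turned negative without anti-CD71 replicate 1 (-0.20 and -0.11), and Gbp2 did so with quantile normalization (-0.03) and without control replicate 2 (-0.02). No other named gene changed sign, and no median of a list that passed did, but fry put the mast cell and eosinophil list as lower with 1 TPM in 1 library. Named genes that did not pass in the main comparison count as keeping their side of the threshold when they stay uncalled. The counts that follow therefore understate how often called genes were lost. With no filter over 4 libraries, 24 named genes fell short and 18 kept their side. Among named genes over 4 libraries, 309 of the values under other settings kept their side of the threshold, 140 fell short of it and 1 passed anew. Leaving out a library gave 91, 63 and 8. Over 3 libraries these were 531, 204 and 12. For lists that passed, the camera adjusted p over 4 libraries kept its side of the threshold in 34 cases and fell short in 17 (13 and 5 with a library left out), and over 3 libraries in 149 and 21. Read depth is unknown, so what depth limits cannot be given.

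Over 4 libraries, genes called higher and lower numbered 2 and 5 with quantile normalization (373 at an unadjusted p under 0.05), 21 and 36 with median scaling, 1 and 0 with no filter (435 at an unadjusted p under 0.05), 2 and 16 with a mean of at least 1 TPM, 1 and 3 with limma without trend, 25 and 81 with robust empirical Bayes, and 43 and 116 at an adjusted p under 0.1. They numbered 10 and 29 where all transcripts of the gene were listed, 2 and 2 with any listed transcript, and 2 and 2 with transcripts in place of genes. Of the 68 calls, 6 were kept with quantile normalization, 1 with no filter, 4 without trend and 66 with robust empirical Bayes. Leaving out 1 library gave from 1 to 36 higher and from 0 to 61 lower, the lowest without control replicate 1 (1 higher, 0 lower, 271 at an unadjusted p under 0.05) or control replicate 2 (2 higher, 0 lower, 171).

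With the replicate number as a block, 2 genes were higher and 1 lower, and 3 of the 68 calls were kept. The numbers were not taken as pairs, a choice fixed beforehand, because the labels do not say that they mark a shared litter, day or batch. In a later check, libraries with the same number did not deviate together (r = -0.006 across 1564 genes, which are not independent).

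Lists that rose over 4 libraries numbered 0 with quantile normalization, 1 with median scaling, 0 with no filter, 0 where all transcripts of the gene were listed, 5 with at least 50% of the TPM listed, 0 with camera at an estimated correlation and 0 with fry. Lists that fell numbered 1 with quantile normalization, 1 with no filter, 1 with a mean of at least 1 TPM, 0 where all transcripts were listed, 4 with any listed transcript, 0 at an estimated correlation and 0 with fry. Leaving out 1 library gave from 0 to 4 lists that rose and from 1 to 3 that fell, and by fry from 0 to 1 in each direction. Listed genes called when adjusted over the lists alone numbered 12 with quantile normalization, 1 with no filter, 13 where all transcripts were listed, 38 with at least 50% listed, and from 2 to 31 with 1 library left out.

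Over 3 libraries, genes called higher and lower numbered 10 and 34 with quantile normalization, 35 and 172 with median scaling, 60 and 12 with at least 1 TPM in 1 library, 0 and 0 with no filter (3401 at an unadjusted p under 0.05), 79 and 31 with a mean of at least 1 TPM, 13 and 22 without trend, 145 and 457 with robust empirical Bayes, and 396 and 804 at an adjusted p under 0.1. Entering anti-CD71 replicate 1 where listed gave 50 and 261, with 270 of the 343 calls kept. Lists that rose numbered 3 with quantile normalization, 4 with median scaling, 4 with a pseudocount of 0.1, 3 without trend, 0 at an estimated correlation and 0 with fry, but fry gave 2 with at least 1 TPM in 1 library and 4 with no filter. Lists that fell numbered 0 at an estimated correlation and 0 with fry. Listed genes adjusted over the lists alone numbered 71 with no filter. The adjusted p of Tfrc ranged from 0.117 to 0.349. Leaving out a control here leaves 1 library per group and no residual degrees of freedom, so it was not run. Genes not listed set to 0 was not run, because the partial file breaks off inside a line. Leaving out globin and immunoglobulin genes was not run over 4 libraries, where it removes no tested gene, and count-based alternatives were not run on TPM.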

Other observations

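Of the tests of explanations below, only that of skin appendage genes was fixed before its values were seen; the others were chosen afterwards.

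Type I interferon response genes were high in anti-CD71 replicate 1 alone. All 8 members of the list with at least 50% of their TPM listed for that library and a mean of at least 1 TPM lay above the mean of the controls there, with a median log2 difference of 1.37, against 0.11 in anti-CD71 replicate 2. Ifit3 transcripts stood at 107.34 and 93.69 TPM in controls, 331.26 TPM in anti-CD71 replicate 1 and 107.25 TPM in replicate 2, and Usp18 at 46.29, 35.63, 123.14 and 43.77 TPM. The 2 anti-CD71 libraries thus differed in this antiviral programme, and the difference was not tested, since each is a single library. Nos2, the inducible nitric oxide synthase gene, was high in both, at 14.84 and 9.34 TPM over the transcripts listed for all 4 libraries, against 2.49 and 0.98 TPM in controls.

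Skin genes were high in anti-CD71 replicate 2. Among 39 hair follicle, melanocyte and sebaceous gland genes, written down before their values were looked up, 36 (92.3%) had their highest value there. Krtap8-1 was highest at 39.38 TPM, and no control was above 2.26 TPM. A share of 33.3% by chance for 1 of 3 libraries holds only for genes that vary independently, which genes of a shared tissue may not. Counting only genes at least 1 TPM above both controls, chosen after the values were seen, 24 of 39 (61.5%) remained: 23 of 27 hair follicle, 1 of 7 melanocyte and 0 of 5 sebaceous gland genes. Among these classes the rise was thus mostly one of hair follicle genes. By the same count 16 of 21 cornified skin genes and 17 of 30 keratinocyte genes rose too. Keratinisation of tumour cells shared by the treated tumours was not seen in the 3 cornified skin genes listed for replicate 1, with a median log2 difference of -0.03. These genes cannot decide it, since Krt25 was at 0 in the controls and replicate 1. Sprr1a stood at 19.47 and 22.39 TPM in controls and 20.43 TPM in replicate 1. Krt16, outside these 3, was above both controls in replicate 1 (3.69 TPM against 2.37 and 1.46 TPM). Of 13 appendage genes listed for replicate 1, 1 lay above both controls. Overlying skin in the piece sampled for replicate 2 is a candidate explanation. A change confined to that tumour and a shared keratinisation stay open.

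S100a9 and some other neutrophil genes were high in the treated tumours, while Ctsg was lower in both. Skin was considered as the source of S100a9 in replicate 1, where S100a9 stood at 142.39 TPM. The highest log2 difference among the 3 cornified skin genes listed there was 0.0, that of Krt25, listed at 0 in controls and replicate 1. Of the 13 appendage genes listed there, 1 lay above both controls, and Krt16 was above both as well. Skin with hair follicle genes, as in replicate 2, was thus not seen in replicate 1. These few genes cannot exclude other skin as the source. More neutrophils in the treated tumours may account for part of the pattern: 14 of 21 list members (66.7%) were above both controls in replicate 2, which is the lowest share that the test counted as a rise, but 10 by at least 1 TPM, and Cxcr2 stood at 1.16 and 1.5 TPM in the treated libraries against 0 in both controls over its shared transcripts. Mmp9 (51.94 and 76.33 TPM in controls, 59.62 TPM in replicate 2) did not follow, and the list did not pass over 4 libraries (adjusted p = 0.0751). In replicate 2, skin may also supply part of S100a8, S100a9 and stefin A transcripts, so a rise in neutrophil activity, number or skin content remains open.

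Macrophage and MHC class II genes were lower. Dilution of tumour RNA by skin RNA would lower the proliferation list too if only tumour cells express it, which was assumed and not tested. The median log2 difference of that list in replicate 2 was 0.19, while that of the macrophage list was -0.70. These values argue against dilution only under that assumption. Csf1r was also lower in replicate 1 (69.38 TPM), where the 3 cornified skin genes listed were not raised. A lower share of all leukocytes cannot be told apart from a change in macrophages: the neutrophil list had a median log2 difference in replicate 2 of 1.83 with the filter of 1 TPM in 1 library and 0.40 with 1 TPM in 2 libraries. The former filter admits 7 of 14 genes through replicate 2 alone, so that median decides nothing, skin may supply part of it, and 3 genes of the list were listed for replicate 1. Whether the composition of the sampled piece bears on the cytotoxic and globin lists (medians -1.90 and -1.57) was not tested. An effect of the antibody on macrophages, and differences between single tumours unrelated to treatment, stay open.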
